A study of Caenorhabditis elegans with 6 samples.

How the data were processed

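Whole hermaphrodites of strain N2 were sampled 5 days after the last larval stage, and total RNA was made into libraries with Illumina's TruSeq kit version 2, a kit that does not mark strand, per the labels' protocols. The 6 libraries were put into 2 groups of 3 from the perturbation each sample's labels give, L4440 or T25B9.1. Another label field names T25B9.1 RNAi for all 6, as the series title does, and was not used for grouping. The labels give no replicate numbers, so libraries were numbered within each group in accession order and never paired by that number.

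The deposited counts are whole numbers of reads per gene, made by the authors with bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4 on genome build WBcel235, per the submitters' processing notes. Whether featureCounts used strand, and how it treated reads of more than 1 gene, is not given in the sources used here. Reads of near-identical copies and of overlapping or antisense genes are therefore uncertain. A deposited RPKM table (reads scaled to gene length and library total by the authors, from the same 6 libraries) was used only for alternatives. In that table the ratio of count to RPKM was taken relative to that of L4440 replicate 1, so that the gene's length cancels. It was not constant within a library but followed the row number with a period of 36 rows. The SD of its log2 was 4.35e-05 within a row class, against 0.177 for the next best period and 0.272 over all rows. Row classes were then counted on from library to library in the order of the numbers in the titles. At the class equal to a library's number, the divisor, with the gene's length divided out, matched that library's total within 0.0383%. Values of the table differ from those scaled to each library's own total by up to 1.78-fold (median 1.18-fold). No column of either table belonged to another sample.

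Totals ran from 25480225 to 38621940 counts per library. Intervals on single counts are exact Poisson intervals at 95% and cover counting error only. Pairs of libraries of the same group differed by 6.18 to 39.7 times the chi-square of sampling noise per degree of freedom, so none was treated as a duplicate. Gene identifiers were named from a table of symbols (43693 of 46748 matched), and positions were taken from Ensembl release 115 of the same build (46449 matched).

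The main test was edgeR's quasi-likelihood F-test (version 4.0.16 in R 4.3.3, robust fit, TMM factors, filterByExpr by group with a minimum count of 10), with Benjamini-Hochberg adjustment and a threshold of 0.05. It was run on the counts as deposited, with no covariate, over 13494 genes (28.9%), of which 12871 are annotated as protein-coding. The common biological coefficient of variation was 0.0929. Standard errors are the log2 fold change divided by the square root of F. Levels are CPM, counts scaled to the library total with TMM factors. An exact permutation test of 3 against 3 cannot go below 0.1, so single genes were tested only by the model over all genes. The test was also run on simulated data with the means, dispersions and library sizes of this comparison. There were 5 runs of 13317 genes on average, with 200 changed genes in each. It recovered 57.0% of changes of 1.5-fold, 83.0% of 2-fold and 98.4% of 4-fold. Of its calls 8.20% were false, above the share of 0.05 that the threshold aims at. Genes were simulated independently, so these shares do not cover genes that vary together. With no list effect simulated, 1 gene list was called by camera over the 5 runs.

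Gene lists, 37 in number, were fixed before the data were examined, with the target left out of each. Some genes, such as clec-85, belong to more than 1 list and are counted in each, so the lists are not independent. They cover stress responses, detoxification, metabolism, immunity, insulin signalling, cuticle, yolk, germline, other tissues and basic machinery. Of these, 36 had at least 5 tested members; the mitochondrially encoded genes could not be matched by name, and the share of counts from the mitochondrial chromosome is given instead. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01), which compares a list with the other genes, then with an estimated correlation and with fry, which asks whether a list moves on balance one way. Benjamini-Hochberg adjustment ran over the 36 lists. Genes named in the text were chosen by a rule also fixed before the data were examined. It takes the target and tested genes of its cosmid. It takes the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 50 counts and no overlap between groups. It takes up to 4 genes of smallest p from each list, and a few preset stress and methylglyoxal genes whatever their p.

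Alternatives fixed before the data were examined were RLE and upper-quartile factors, no filter on low counts, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, limma with trend on log2(RPKM + 1) and log2(RPKM + 0.1), a block of consecutive library numbers in the titles, a 2-fold minimum, and leaving out each library in turn. RPKM rescaled to each library's own total was added after seeing the data. Fold changes from RPKM are on the log2(value + pseudocount) scale and understate changes of low genes.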

Results

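RNA was sequenced from whole Caenorhabditis elegans hermaphrodites of the wild-type strain N2, 5 days after the last larval stage. By their labels, 3 libraries came from animals under feeding RNAi against T25B9.1, in which the animals eat bacteria that make double-stranded RNA against a chosen gene. The labels of the other 3 name L4440, the plasmid without an insert, which serves as the control. T25B9.1 is the worm's predicted glycine C-acetyltransferase, an enzyme of threonine breakdown. The question was which transcripts differ when this gene is targeted in adult animals. Between 25480225 and 38621940 reads were counted in genes per library. The L4440-labelled libraries held 35642482, 25480225 and 38621940 counts and the libraries labelled T25B9.1 held 31741182, 26141547 and 34659131. At least 10 counts were found for 12778 to 13752 genes in each library.

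The targeted gene was measured first, since its level bears on the labels. T25B9.1 (WBGene00012007) lies on chromosome IV at 10748378 to 10750141, minus strand, in build WBcel235, and its gene model overlaps the end of T25B9.3 on the other strand by 24 bases. It had 90, 92 and 132 counts in the L4440-labelled libraries and 219, 317 and 430 in the libraries labelled T25B9.1. The normalised levels were 3.19 ± 0.552 CPM (SD, n = 3), that is, counts scaled to the library's normalised total, and 10.5 ± 3.29 (SD, n = 3). T25B9.1 was thus 3.31-fold higher in the libraries labelled with its own RNAi (log2 fold change 1.73, SE 0.245, edgeR adjusted p = 0.00483), and each of these 3 libraries lay above each of the L4440-labelled ones. The counting intervals of single libraries reached at most 4.52 CPM under the L4440 label and began at 5.87 or above under the T25B9.1 label. The target was therefore not lower where its RNAi was labelled. Counts per gene cannot tell an exchange of all labels from a true rise or from reads of the double-stranded RNA fed to the animals. Each direction given here is that of the libraries labelled T25B9.1 relative to those labelled L4440. No other tested gene of the same cosmid passed the test by edgeR: T25B9.5, T25B9.8, T25B9.9 and T25B9.12 had log2 fold changes of -0.51, 0.01, -0.17 and -0.25.

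**Figure D1:**
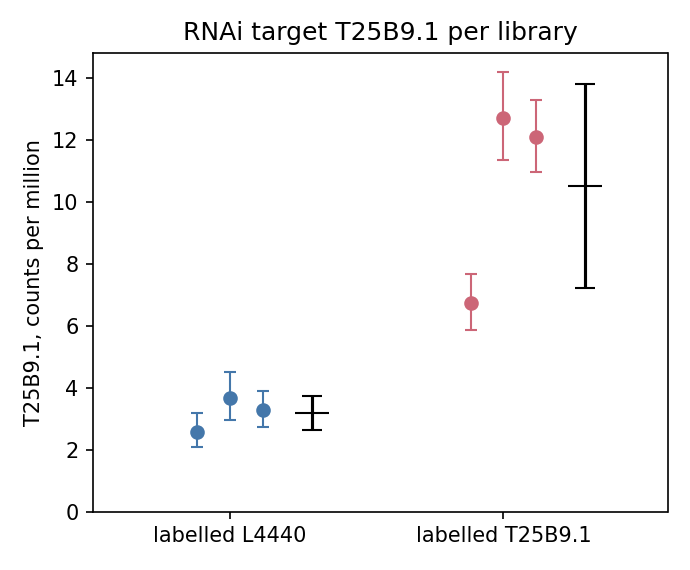
T25B9.1 in CPM (vertical axis) for each library, with the 2 label groups on the horizontal axis; coloured bars are 95% Poisson counting intervals, and black marks are group means with SD (n = 3). The libraries labelled T25B9.1 lie at 6.73 or higher, all above the L4440-labelled libraries at 2.59, 3.68 and 3.28.

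Of 13494 genes tested, 461 passed an adjusted p of 0.05 by edgeR, 152 higher and 309 lower in the libraries labelled T25B9.1. Among genes past the threshold with a mean of at least 50 counts and no overlap between groups, the largest falls of named genes were in folt-2, a folate transporter (log2 fold change -2.57, SE 0.208), acdh-1, an acyl-CoA dehydrogenase (-2.52, SE 0.310), C35A5.3 (-2.39, SE 0.197) and acs-2, an acyl-CoA synthetase of fatty acid oxidation (-2.28, SE 0.314). The ammonium transporter gene amt-1 (-2.18, SE 0.166) and the fatty acid binding protein gene lbp-8 (-1.96, SE 0.144) were also lower. Among the genes that rose, scl-2, which encodes a secreted SCP/TAPS-domain protein, went from 18.7 ± 3.35 to 83.4 ± 2.76 CPM (SD, n = 3), a 4.49-fold difference. The acid sphingomyelinase gene asm-3 (log2 fold change 1.97, SE 0.154), the short-chain dehydrogenase gene dhs-26 (1.71, SE 0.140), C14C6.5 (1.87, SE 0.146) and cyp-14A3 (2.02, SE 0.198) rose as well. F42A10.7 (2.60, SE 0.473) and thn-1, a thaumatin-like gene (2.52, SE 0.399), had the largest rises by the same rule, with a wide spread between libraries. In build WBcel235, folt-2 lies on chromosome V at 2872465 to 2875600, acdh-1 on chromosome I at 6497436 to 6499560 and scl-2 on chromosome IV at 13057710 to 13059062.

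The genes past the threshold were 3.42% of those tested. At least a 2-fold change was reached by 139 of them, 70 higher and 69 lower, and 456 were protein-coding. The 2 groups of libraries did not overlap for all 461 genes, and for 2414 of the tested genes (17.9%, where chance gives 10%). The first principal component held 40.1% of the variance and separated the label groups. The labels do not say whether the libraries came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Several of the largest changes did not pass without 1 library or under another setting. The fall of acdh-1 had an edgeR adjusted p of 0.0750, 0.0815 and 0.0794 without L4440 replicate 1, 2 and 3, and that of acs-2 had 0.0511 without L4440 replicate 2 and 0.102 without T25B9.1 replicate 2. Without L4440 replicate 1, 2 and 3 and T25B9.1 replicate 2, the edgeR adjusted p was 0.0957, 0.0900, 0.168 and 0.133 for thn-1 and 0.152, 0.153, 0.261 and 0.0615 for F42A10.7. With no filter on low counts the edgeR adjusted p was 0.0575 for acdh-1, 0.0986 for acs-2, 0.146 for thn-1 and 0.177 for F42A10.7, which also lost its call with upper-quartile factors (0.0502), by limma-voom (0.0659) and on rescaled RPKM (0.0576). Reads could be shared with an overlapping gene model for several genes of this report: T25B9.1, T25B9.12, amt-1, C35A5.3, asm-3, dhs-26, cyp-14A3, gst-4, ugt-21, gpd-2, alh-8, hsp-17, clec-85, col-143, vit-3, vit-4, asp-4, marg-1, fip-2 and sod-3.

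**Figure D2:**
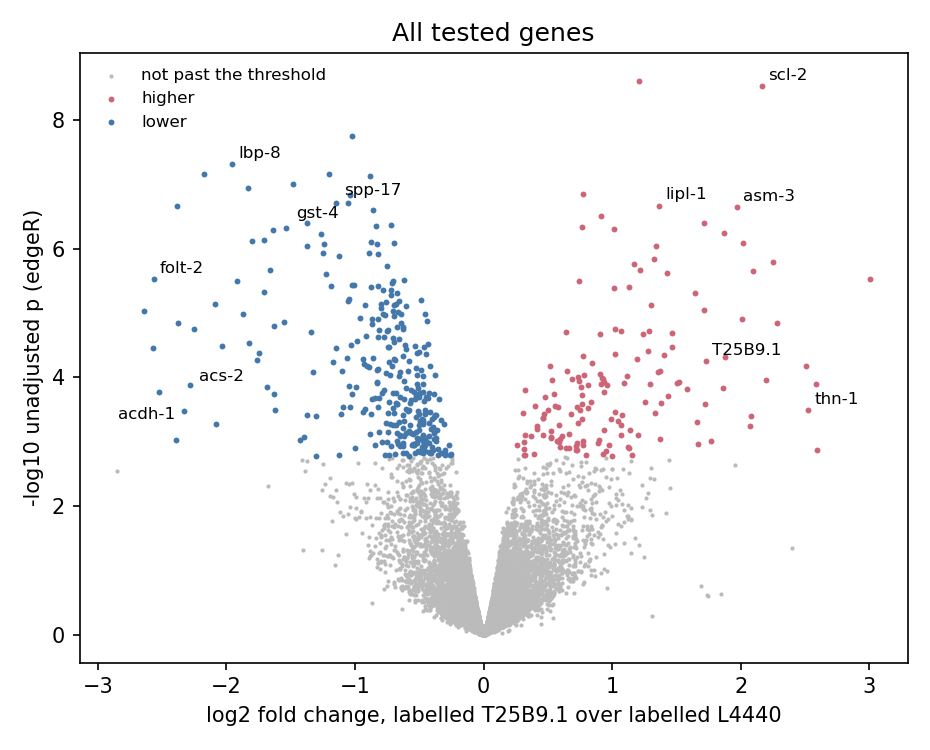
Log2 fold change (horizontal axis, libraries labelled T25B9.1 over those labelled L4440) against -log10 of the unadjusted edgeR p (vertical axis) for each of 13494 tested genes. Coloured points are the 152 genes that were higher and the 309 that were lower at an adjusted p under 0.05, and grey points are the rest.

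**Figure D3:**
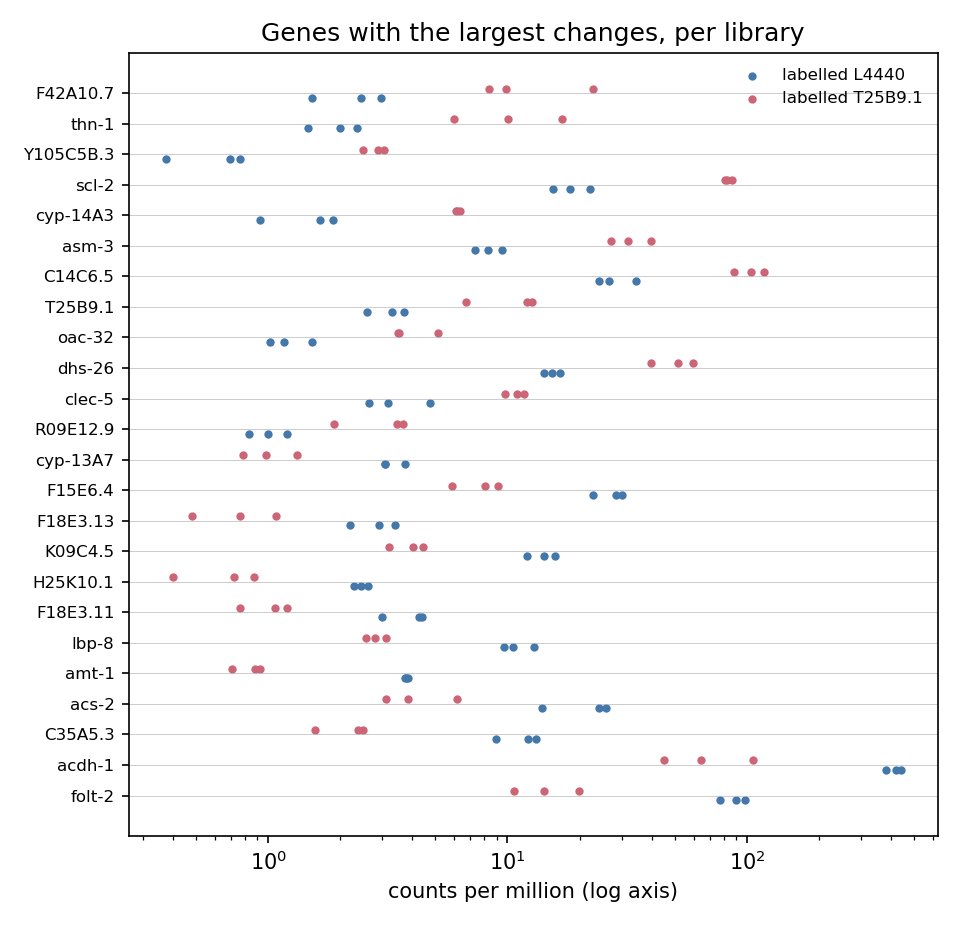
CPM on a log axis (horizontal) for the 12 named genes with the largest rises and the 12 with the largest falls (vertical), chosen among genes with a mean of at least 50 counts, with 1 point per library (n = 3 per label). For each gene the points of the 2 label groups do not overlap.

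Among the genes of lipid metabolism that passed, more fell than rose. Of 51 tested members of the fixed list, 12 were lower and 3 higher in the libraries labelled T25B9.1 (14 lower and 3 higher adjusted over the list alone), with a median log2 fold change of -0.19 (-0.12 without L4440 replicate 3). Besides acdh-1, acs-2 and lbp-8, the peroxisomal acyl-CoA oxidase gene acox-1.5 fell (-0.70, SE 0.0685). Of the 12 lower genes, acdh-1 and ech-6 also act in propionate breakdown. In the other direction, the lysosomal lipase gene lipl-1 rose (1.36, SE 0.117) and so did fat-3, the delta-6 desaturase gene (0.76, SE 0.0706). The list passed by camera (adjusted p = 3.27e-05) and by fry (adjusted p = 0.0130), and not with an estimated correlation (adjusted p = 0.397). In the list of glycolysis, gluconeogenesis and the glyoxylate shunt, 3 of 23 members were lower and none higher (4 lower adjusted over the list alone). They were the glyoxylate shunt gene icl-1 (-0.82, SE 0.104) and the glyceraldehyde-3-phosphate dehydrogenase genes gpd-2 (-0.45) and gpd-3 (-0.44), which are near-identical copies. This list had a camera adjusted p of 0.00772 (adjusted p = 0.893 with an estimated correlation), and of 0.149 without L4440 replicate 2 and 0.0800 without T25B9.1 replicate 1.

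Among the enzymes that join glutathione or a sugar to foreign and endogenous compounds, each one that passed was lower in the libraries labelled T25B9.1. Of 36 tested glutathione S-transferases, 5 were lower and none higher (13 lower and 1 higher adjusted over the list alone), 32 had a negative log2 fold change, and the median was -0.36. Here gst-4, a widely used reporter of the oxidative stress response, fell from 20.5 ± 3.70 to 7.01 ± 0.750 CPM (SD, n = 3), and gst-13 had a log2 fold change of -0.77 (SE 0.0990). The list passed by camera (adjusted p = 5.43e-08; adjusted p = 0.604 with an estimated correlation). Of 58 UDP-glucuronosyltransferases, 11 were lower and none higher (13 lower adjusted over the list alone) and 19 had a positive log2 fold change. The falls were led by ugt-62 (-1.48, SE 0.107), ugt-19 (-1.23, SE 0.135), ugt-21 (-1.03, SE 0.150) and ugt-44 (-0.89, SE 0.0682), with a camera adjusted p of 0.000301 (adjusted p = 0.893 with an estimated correlation). The cytochrome P450s went both ways, with 6 of 62 higher and 7 lower (10 and 12 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.223, and 0.0489 without T25B9.1 replicate 1). There cyp-32B1 rose (1.13, SE 0.130) and cyp-34A8 fell (-0.96, SE 0.125), as did cyp-13A7 (-1.71, SE 0.201), whose reads can be shared with its paralogs. Of 27 redox enzymes, gpx-3, a glutathione peroxidase gene at about 1 CPM, was higher (1.44, SE 0.258; edgeR adjusted p = 0.0531 without L4440 replicate 2) and none was lower (2 higher adjusted over the list alone; camera adjusted p = 0.256).

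Genes of the target's pathway and of aldehyde detoxification were measured in 2 lists. In the list of threonine, glycine and one-carbon metabolism, 2 of 23 tested genes were lower in the libraries labelled T25B9.1 and none higher (4 lower adjusted over the list alone): sams-1, an S-adenosylmethionine synthetase gene (-0.89, SE 0.0908), and gldc-1, of the glycine cleavage system (-0.49, SE 0.0595). The threonine dehydrogenase gene F08F3.4, which acts before the target in threonine breakdown, had a log2 fold change of -0.23 (SE 0.0704, edgeR adjusted p = 0.139). The list's camera adjusted p was 0.0477 (adjusted p = 0.893 with an estimated correlation); it was 0.334, 0.111 and 0.162 without L4440 replicate 2, T25B9.1 replicate 1 and T25B9.1 replicate 3, and 0.0507 with a mean of at least 50 counts. The median was -0.0406, and 0.00438 without L4440 replicate 2, -0.0718 and -0.0772 without L4440 replicate 1 and 3, and -0.106 without T25B9.1 replicate 2. Of 17 genes that detoxify aldehydes and methylglyoxal, hphd-1 (-1.70, SE 0.138) and alh-8 (-0.43, SE 0.0758) were lower and none was higher (4 lower adjusted over the list alone). Both act in propionate breakdown rather than on methylglyoxal. The glyoxalase gene glod-4 (-0.17, SE 0.0687) and djr-1.1 (0.02, SE 0.0870) and djr-1.2 (-0.69, SE 0.297), of the DJ-1 family, did not pass by edgeR (adjusted p = 0.316, 0.955 and 0.347). The camera adjusted p of this list was 0.0171 (adjusted p = 0.604 with an estimated correlation). It was 0.114 without L4440 replicate 2 and 0.0928 without T25B9.1 replicate 3, and alh-8 had an edgeR adjusted p of 0.0668 without T25B9.1 replicate 1.

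**Figure D4:**
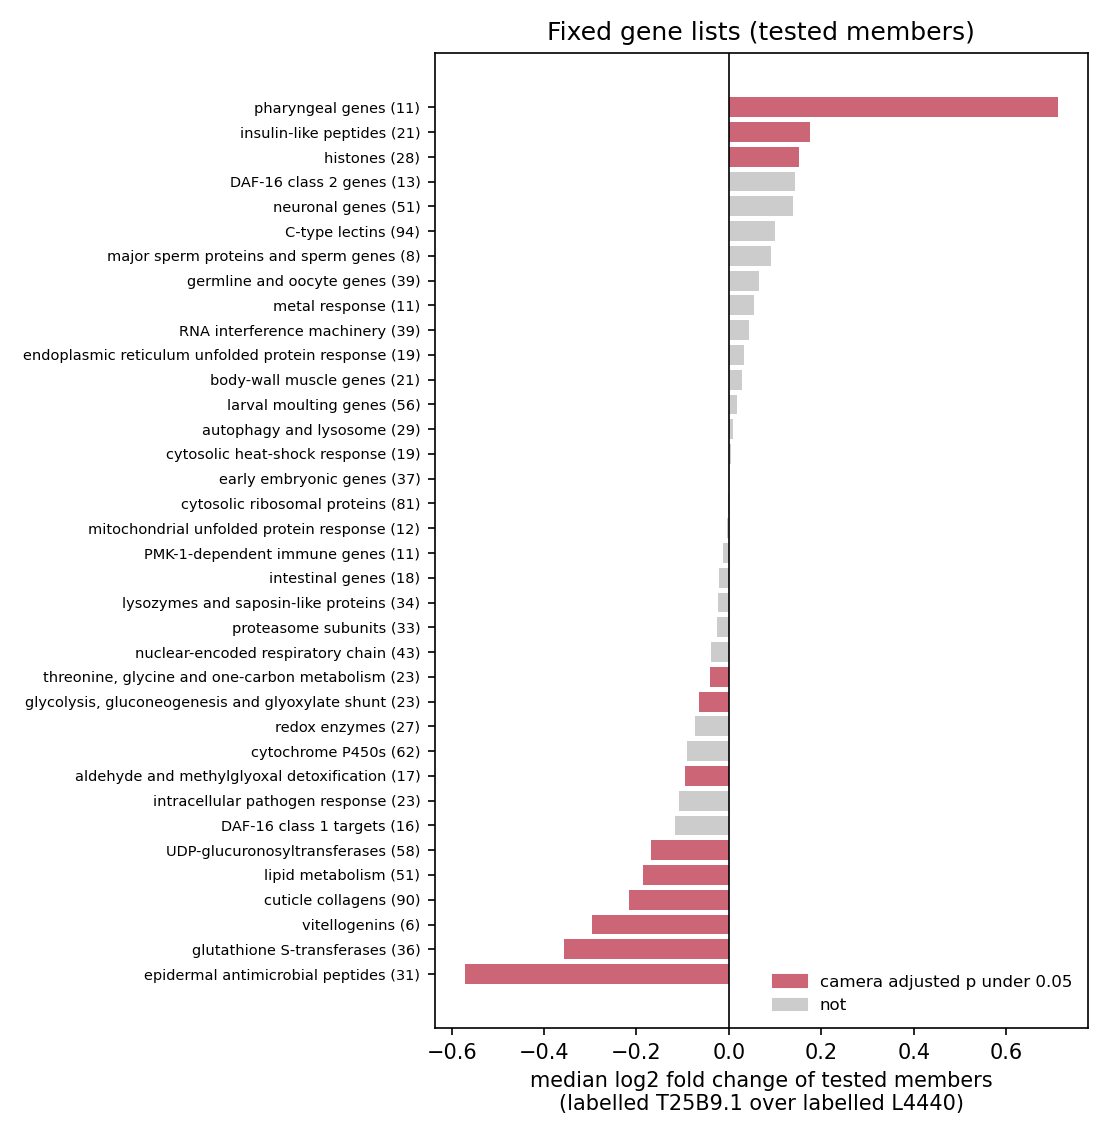
Median log2 fold change of the tested members (horizontal axis) for each of 36 fixed gene lists (vertical axis, number of tested members in brackets), libraries labelled T25B9.1 over those labelled L4440. Red bars are the 12 lists with a camera adjusted p under 0.05, 9 lower and 3 higher; none of them passed with an estimated correlation.

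No list of protein quality control genes passed by camera with all libraries, those labelled T25B9.1 against those labelled L4440. Of 19 cytosolic heat-shock genes, hsp-17 (-0.62, SE 0.105) and hsp-16.48 (-0.77, SE 0.183), which has a near-identical copy, were lower and none was higher (2 lower adjusted over the list alone; camera adjusted p = 0.868). The call of hsp-16.48 was lost without each library but L4440 replicate 1, with edgeR adjusted p-values of 0.160 and 0.191 without L4440 replicate 2 and 3, and 0.154, 0.123 and 0.0723 without T25B9.1 replicate 1, 2 and 3, and also with a mean of at least 50 counts (0.0576) and by limma-voom (0.0666). The inducible genes hsp-16.2 (0.24, SE 0.190) and hsp-70 (0.15, SE 0.130) did not pass (edgeR adjusted p = 0.700 and 0.744). By edgeR, none of 33 proteasome subunits, 19 genes of the endoplasmic reticulum unfolded protein response, 12 of the mitochondrial one and 29 of autophagy and the lysosome passed. Their median log2 fold changes were -0.03, 0.03, -0.0044 and 0.0079, with camera adjusted p-values of 0.639, 0.227, 0.823 and 0.823. Most members of the first 2 lists had the same sign. Of the proteasome subunits 26 were negative and 7 positive, and of the endoplasmic reticulum genes 3 were negative and 16 positive. The proteasome median was 0.06 without L4440 replicate 2 (camera adjusted p = 0.0279) and -0.10 without L4440 replicate 3 (camera adjusted p = 0.0190). Both calls use the preset correlation of 0.01, while the correlation estimated for this list was 0.877. With that estimate and all libraries the camera adjusted p was 0.933.

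Genes of immune effector families were measured in 5 lists. Of 94 tested C-type lectins, 8 were higher and 11 lower in the libraries labelled T25B9.1 (15 and 16 adjusted over the list alone; camera adjusted p = 0.638), among them clec-5 (1.64, SE 0.189), clec-258 (1.29, SE 0.177) and clec-160 (-0.72, SE 0.0815). Among 34 lysozymes and saposin-like proteins, 4 were higher and 2 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.739). The lysozyme gene lys-7 rose from 1169 ± 257 to 2229 ± 203 CPM (SD, n = 3), while spp-17 fell from 249 ± 29.7 to 113 ± 10.1. Of 31 epidermal antimicrobial peptides, 1 was higher and 4 lower (2 and 10 adjusted over the list alone), 26 had a negative log2 fold change, and the median was -0.57, or -0.38 without L4440 replicate 3 (camera adjusted p = 1.12e-05; adjusted p = 0.893 with an estimated correlation). The higher gene, abf-5, did not pass without L4440 replicate 1, 2 or 3 (edgeR adjusted p = 0.0828, 0.0649 and 0.118) or without T25B9.1 replicate 1, 2 or 3 (0.0956, 0.0508 and 0.111). Of the lower genes, fip-2 had 0.0594 and 0.104 without L4440 replicate 2 and 3 and 0.0616 and 0.0687 without T25B9.1 replicate 2 and 3. For fipr-26 these were 0.114 and 0.127 without L4440 replicate 2 and 3, 0.120 and 0.0612 without T25B9.1 replicate 1 and 2, and 0.0557 by limma-voom. For fipr-1 they were 0.0977 and 0.154 without L4440 replicate 1 and 3, 0.111 and 0.0746 without T25B9.1 replicate 1 and 2, 0.225 with no filter on low counts and 0.0631 on rescaled RPKM. Of 11 PMK-1-dependent immune genes, 1 was lower, clec-85 (-0.38, SE 0.0685; 3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.638), with an edgeR adjusted p of 0.0516 without T25B9.1 replicate 3. Of 23 genes of the intracellular pathogen response, 1 was lower, skr-4 (-0.71, SE 0.0896; 3 lower adjusted over the list alone; camera adjusted p = 0.171). Among its members with a mean of at least 50 counts, this list passed at the preset correlation (median -0.31, camera adjusted p = 0.00445). With all its tested members and an estimated correlation, its camera adjusted p was 0.904.

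Some cuticle and yolk transcripts were lower in the libraries labelled T25B9.1, and some pharyngeal ones higher. Of 90 tested cuticle collagens, 9 were lower and none higher (18 lower and 3 higher adjusted over the list alone), including col-143 (-0.68, SE 0.0843) and col-101 (-0.70, SE 0.0968), and 36 had a positive log2 fold change. This list had a camera adjusted p of 0.00458 (adjusted p = 0.911 with an estimated correlation), and of 0.682 without L4440 replicate 2 and 0.0639 with no filter on low counts. All 6 vitellogenin genes, which encode yolk proteins, had negative log2 fold changes, and 2 passed (2 adjusted over the list alone), the near-identical vit-3 (-0.79, SE 0.170) and vit-4 (-0.75, SE 0.162). Without L4440 replicate 1, L4440 replicate 3, T25B9.1 replicate 1 or T25B9.1 replicate 3, neither passed (edgeR adjusted p = 0.0892, 0.129, 0.115 and 0.0625 for vit-3 and 0.0596, 0.107, 0.132 and 0.0882 for vit-4); without T25B9.1 replicate 2 vit-3 had 0.0522. Both also lost the call with the block of consecutive library numbers (0.107 and 0.125), and vit-3 with no filter on low counts (0.119). The camera adjusted p of the vitellogenins was 0.0171 (adjusted p = 0.904 with an estimated correlation), and it was 0.198, 0.111 and 0.0883 without L4440 replicate 1, T25B9.1 replicate 1 and T25B9.1 replicate 3. Of 11 pharyngeal genes, 2 were higher and none lower (4 higher adjusted over the list alone), with a median of 0.71 (camera adjusted p = 0.00433; adjusted p = 0.721 with an estimated correlation). With a mean of at least 50 counts the list did not pass (median 0.39, camera adjusted p = 0.114), and without L4440 replicate 3 its median was 0.46. The 2 were abu-10 (2.51, SE 0.397), at under 1 CPM, and marg-1 (0.95, SE 0.222), which lost its call without each library but T25B9.1 replicate 2 (edgeR adjusted p = 0.0902, 0.0507 and 0.197 without L4440 replicate 1, 2 and 3, and 0.172 and 0.132 without T25B9.1 replicate 1 and 3), by limma-voom (0.0515) and on rescaled RPKM (0.0948).

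Markers of other tissues and stages were measured beside these lists, since whole animals mix them. No gene passed by edgeR among 39 germline and oocyte genes (median 0.07, camera adjusted p = 0.0970), 37 early embryonic genes (1.9e-05, 0.639), 8 sperm genes (0.09, 0.739), 21 body-wall muscle genes (0.03, 0.823) and 51 neuronal genes (0.14, 0.0610). Of 18 intestinal genes, 3 were higher and 3 lower (5 and 7 adjusted over the list alone; median -0.02, camera adjusted p = 0.638). The peptide transporter gene pept-1 (0.91, SE 0.123) and the intermediate filament gene ifb-2 (0.74, SE 0.0841) rose, and the protease genes cpr-6 (-0.58, SE 0.0901) and asp-4 (-0.59, SE 0.0952) fell. Of 56 larval moulting genes, grd-5 (-0.74, SE 0.109) and grd-3 (-0.67, SE 0.149) were lower and none higher (4 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.638). The call of grd-3 was lost without L4440 replicate 2, L4440 replicate 3, T25B9.1 replicate 1 or T25B9.1 replicate 2 (edgeR adjusted p = 0.118, 0.121, 0.132 and 0.075). None of 81 cytosolic ribosomal proteins, 43 nuclear-encoded respiratory chain genes and 39 genes of the RNA interference machinery passed by edgeR (camera adjusted p = 0.639, 0.276 and 0.566). Some of these lists passed by camera under other settings. The neuronal genes had an adjusted p of 0.0496 with a mean of at least 50 counts, 0.0169 with the block of consecutive library numbers and 0.0141 without L4440 replicate 3. Without T25B9.1 replicate 2 they had 1.19e-05 (median 0.26), and the ribosomal proteins had 1.94e-07 without L4440 replicate 2. The respiratory chain genes had 0.0284 and 0.0136 without L4440 replicate 1 and 3, and the germline genes 0.0284 without L4440 replicate 1 and 0.0439 on rescaled RPKM. These calls use camera's preset correlation. With an estimated correlation and all libraries, each of these lists had a camera adjusted p of 0.933. The body-wall muscle list passed in no alternative, and its median ran from -0.18 to 0.10 outside deposited RPKM. Mitochondrial transcripts took 0.612%, 0.760% and 0.818% of the counts in the L4440-labelled libraries and 0.721%, 0.521% and 0.698% in those labelled T25B9.1. Ribosomal RNA took 1.22% in T25B9.1 replicate 2 and at most 0.288% elsewhere, and without that library 347 genes passed by edgeR, 128 higher and 219 lower.

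Lists tied to insulin signalling, metals and histones held a few changed genes. Of these, ftn-1, icl-1, gpd-2, lys-7 and ins-7 are each counted in more than 1 list of this report. Of 16 class 1 genes, known to rise with the transcription factor DAF-16, 4 were higher and 3 lower in the libraries labelled T25B9.1 (5 and 5 adjusted over the list alone; camera adjusted p = 0.739), with dod-6 rising (1.02, SE 0.0949) and the ferritin gene ftn-1 falling (-0.87, SE 0.0854). The superoxide dismutase gene sod-3 had a log2 fold change of -0.51 (SE 0.163, edgeR adjusted p = 0.154). Of 13 class 2 genes, known to fall with DAF-16, 1 was higher and 2 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.766), with dod-17 falling (-1.05, SE 0.128). The insulin-like peptide gene ins-7 rose (0.91, SE 0.156) as 1 of 21 tested peptides (2 adjusted over the list alone; camera adjusted p = 0.0477; adjusted p = 0.893 with an estimated correlation). That list had a camera adjusted p of 0.146, 0.114 and 0.191 without L4440 replicate 1, L4440 replicate 2 and T25B9.1 replicate 3, and of 0.0639 with no filter on low counts. In the metal response list 4 of 11 genes were lower and none higher (4 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.663), among them cdr-2 (-0.86, SE 0.123) and cdr-4 (-0.64, SE 0.0848). Of 28 histone genes, 2 were higher and none lower (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00772; adjusted p = 0.893 with an estimated correlation). They were the linker histone genes hil-5 (0.32, SE 0.0752) and hil-7 (0.72, SE 0.167). The histone list had a camera adjusted p of 0.0810 without L4440 replicate 1, and both gene calls were lost without L4440 replicate 3 (edgeR adjusted p = 0.151 and 0.177), T25B9.1 replicate 1 (0.231 and 0.130) or T25B9.1 replicate 3 (0.132 and 0.0819). In addition, hil-5 had 0.133 without L4440 replicate 2, and hil-7 had 0.108 and 0.113 without L4440 replicate 1 and T25B9.1 replicate 2. Across other settings, hil-5 had 0.0540 with a mean of at least 50 counts, 0.0507 by limma-voom and 0.127 on rescaled RPKM, and hil-7 had 0.0533 by DESeq2. The median and the mean log2 fold change differed in sign in the heat-shock, redox, DAF-16 class 1, lysozyme and saposin-like, PMK-1, larval moulting, early embryonic, ribosomal and metal response lists, none of which passed by camera with all libraries.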

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

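The test on rescaled RPKM was chosen after the result was seen; the other alternatives were fixed before the data were examined. T25B9.1 was higher in the libraries labelled with its RNAi, and past an adjusted p of 0.05, in all 16 alternatives by edgeR, DESeq2 or limma, with log2 fold changes of 1.30 to 1.97 and adjusted p-values of 7.5e-12 to 0.0312. Of 83 other named genes past the threshold, 60 kept the call in every alternative that tested them except deposited RPKM, where 56 of the 83 lost it with a pseudocount of 1 and 52 with 0.1. None of the 461 genes changed sign in any of the 16 alternatives that tested it. Of them, 222 passed without each library in turn. With no filter on low counts 719 genes passed, 256 of them higher, with 22684 genes tested. On deposited RPKM 58 genes passed with a pseudocount of 1 (20 higher, 38 lower) and 77 with 0.1 (27 higher, 50 lower); after rescaling to library totals 359 passed, so most of that drop went with the table's scaling. A 2-fold minimum left 139 genes, 70 higher and 69 lower. Leaving out 1 library gave 272 to 517 genes, 88 to 154 higher and 175 to 363 lower, and 8 to 15 lists; the counts without L4440 replicate 2, L4440 replicate 3 and T25B9.1 replicate 1 were 296, 272 and 307 genes, with fewer samples in the fit. Of 12 lists past the threshold by camera, 0 passed with an estimated correlation (smallest adjusted p 0.397) and 1 by fry, and 5 passed without each library in turn. With no filter on low counts the camera adjusted p of the collagens and of the insulin-like peptides was 0.0639, and with a mean of at least 50 counts that of the pharyngeal genes was 0.114 and that of threonine, glycine and one-carbon metabolism 0.0507, while the intracellular pathogen response and the neuronal genes passed (0.00445 and 0.0496). The proteasome list's median turned to 0.0610 without L4440 replicate 2 and was -0.102 without L4440 replicate 3; the cause was not tested. The block of consecutive library numbers, a grouping the labels do not state, gave 597 genes, and the deviations of same-block libraries correlated at -0.0514, 0.124 and 0.222. The call of the target rests on 90 to 430 counts per library.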

Other observations

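All tests of explanations in this part, the scan of gene families and the choice of genes outside the fixed lists came after the results were seen. A scan of 127 gene families named by symbol, each with at least 10 tested members, found 6 past a camera adjusted p of 0.05 and 0 with an estimated correlation (adjusted p = 0.977). Beyond the transferases and collagens described above, the F-box families differed in the sign of their medians. The fbxa family had a negative median in the libraries labelled T25B9.1 relative to those labelled L4440 (1 member higher, 2 lower and 101 not past the threshold for single genes by edgeR, median log2 fold change -0.18, camera adjusted p = 8.03e-06). The fbxb family had a positive median (91 tested, none past the threshold for single genes by edgeR, median 0.23, camera adjusted p = 0.00128). The transthyretin-like ttr family had a negative median (46 tested, 1 higher and 4 lower, median -0.16, camera adjusted p = 0.00911).

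All 5 genes of the propionate shunt, which breaks down propionate without vitamin B12, were lower in the libraries labelled T25B9.1: acdh-1, hphd-1, hach-1 (-0.72, SE 0.0662), ech-6 (-0.60, SE 0.0753) and alh-8. The nuclear receptor genes nhr-68, an activator of the shunt (-0.82, SE 0.0942), and nhr-114 (-0.94, SE 0.143) and the transporter gene pmp-5 (-1.12, SE 0.115) were lower too, each past an edgeR adjusted p of 0.05. Of the regulators looked at, nhr-10 did not pass (-0.12, SE 0.0819, edgeR adjusted p = 0.642). None of the 4 genes of the B12-dependent route, pcca-1, pccb-1, mce-1 and mmcm-1, passed by edgeR, with log2 fold changes of 0.02, -0.04, -0.01 and 0.05.

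Without each library in turn, the mean log2 change of the 5 shunt genes stayed between -1.31 and -1.13. All 5 passed with groups that did not overlap, so leaving out 1 library could hardly turn their sign. These genes were also chosen after the results were seen. The range therefore gives only the size of their mean fall and is no test of 1 library alone. Both acdh-1 and alh-8 lost their own call without single libraries, as given in the report. A fall shared by most of 11 methionine and folate cycle genes was not seen. The lower genes nhr-114 and pmp-5 were not among these 11. Their median log2 fold change was -0.0446, and 2 passed by edgeR, folt-2 and sams-1, both lower. Those 2 mostly set the mean of -0.349 (SE over genes 0.236). That SE is over genes, not libraries, so whether a fall of part of these genes goes with the shunt stays open.

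T25B9.1 was higher in the libraries labelled with its RNAi. An exchange of 1 library with 1 of the other group is argued against, since the 9 splits that move 1 library of each group gave 0 genes past the threshold at most, against 461 by the labels. An exchange of all labels of the 2 groups cannot be told apart from a true rise: the lowest library labelled T25B9.1 stood 1.83 times above the highest L4440-labelled one, which either would give. Reads of the double-stranded RNA fed to the animals may also add to the count; no other tested gene of the cosmid rose (largest log2 change 0.00745), but counts per gene hold no read positions, so this stays open.

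The lists of glutathione S-transferases and UDP-glucuronosyltransferases both had negative medians, with 5 of 36 and 11 of 58 members lower by edgeR and neither list past the threshold with an estimated correlation. Both lists passed by camera without each library in turn (largest adjusted p 0.0436, for the UDP-glucuronosyltransferases without T25B9.1 replicate 2). These calls use the preset correlation, while the correlations estimated for these lists were higher, at 0.156 and 0.227. They therefore cannot decide whether a single library gave the pattern. Outside deposited RPKM, the medians stayed at or below -0.255 and -0.0986, so leaving out a single library did not turn their sign. Fewer intestinal transcripts in the libraries labelled T25B9.1 could also lower these transcripts. The 18 genes of the intestinal list showed no general fall: 3 were higher and 3 lower by edgeR, with a median log2 fold change of -0.0224. That median lay 0.217 above that of the 94 enzyme genes, with a 95% bootstrap interval of -0.0855 to 0.413. The interval comes from resampling genes, not libraries, so it leaves open a loss limited to part of the intestinal transcripts. A response to the RNAi itself stays among the open explanations, untested.

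The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The split by labels gave 461 genes, the highest other split 0, and 1 of the 10 splits, the real one, gave as many.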
